A study of Mus musculus with 8 samples.

How the data were processed

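RNA-seq libraries were made from the white part of the quadriceps, a muscle of mostly fast glycolytic fibres, of 8 male mice aged 11 to 14 weeks. Every mouse had been fasted for 14 h overnight before the tissue was taken in the morning. Of these, 4 carried only the floxed Acot2 alleles (floxed control, replicates 1 to 4) and 4 also carried Cre recombinase under the muscle creatine kinase promoter, which removes the floxed part of the gene in muscle fibres (Acot2 muscle knockout, replicates 5 to 8). The titles give each library its own mouse number, so the replicates were taken as separate animals. Replicate numbers run over the series and pair no mice. A group of mice with Cre but without floxed alleles was not analysed here, so an effect of Cre itself cannot be separated from loss of Acot2. The labels give no sequencing batch or date.

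Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded TruSeq kit. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq and DESeq2 without versions, and the mouse build GRCm38. The annotation release, the strand setting of the counting and the filters are not given in the sources used here. The deposited table holds log2 values for 54091 gene rows and 8 libraries. From the values themselves, each deposited log2 value is log2(n + 1), where n is a gene's read count divided by 1 size factor per library, with no scaling for gene length. Taking 2 to the power of the value and subtracting 1 gave multiples of 1 step per library. Of the values up to 200 reads, 100% lay within 0.1 read of a whole number in every library. Reads on genes recovered this way ranged from 28659632 to 40977866 per library. Of the rows, 28495 were 0 in every library and 16261 had no Entrez gene ID. In 27 rows the symbol had been turned into a date, and 2 symbols were shared by more than 1 row; none of these was named. All per-sample columns were matched to a library by the mouse number in the column name.

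The pseudocount of 1 is the one already in the deposited values, so fold changes are on the log2(n + 1) scale, which understates changes of low genes. Genes with a mean normalized count of at least 10 over the 8 libraries were tested, which left 13141. Genotype was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) with Benjamini-Hochberg adjustment over those genes, and a gene was called at an adjusted p under 0.05. Standard errors are those of the moderated limma fit. The targeted gene was also compared with an exact two-sided permutation test over the 70 assignments of 4 libraries against 4, whose smallest possible p is 0.0286. Gene lists were fixed before the data were examined: 27 pathway lists and 12 lists of cell type markers, with 739 entries, of which 5 matched no row and 2 repeated a gene under another name. Some genes are in several lists. Each list with at least 5 tested genes was compared with the other tested genes by limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 37 lists that had enough genes. The same lists were tested with camera using an estimated correlation, with fry, and with an exact permutation test of the list mean per library.

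The genes named below follow a rule fixed with the lists: Acot2, then called genes, and for each list without a called member its 2 genes with the smallest p, given as values. Since fewer than 10 genes were called, the 10 genes with the smallest p are also named as values. Genes with provisional names were not named, and 2 genes that the rule selects are not reported here. Genes named outside the rule, among them Ttn, Vwf, Pecam1, Lyz2, Myh2 and those under other observations, were chosen after their values were seen. Positions are from the GENCODE annotation of GRCm38, counted from 1. Transcript length is that of the longest annotated transcript, which was matched, with its GC content, for 12722 of the tested genes (96.8%).

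The scripts were tested on simulated data before use, with independent genes that had the means and spreads of the real ones. Over 10 simulated comparisons of knockout with control, with 13141 genes and 200 changed genes each, limma called 36.4% of 1.5-fold changes, 62.4% of 2-fold changes and 87.4% of 4-fold changes, and 66 of 1305 calls were genes that had not been changed. With 200 changed genes the Benjamini-Hochberg threshold is looser than where few genes change, so these shares do not carry over to the real comparison. There Acot2, at 19.4% of the floxed control mean, had a limma adjusted p of 0.087. Libraries were compared in pairs by a chi-square test of their recovered reads. The most alike pair, floxed control 4 and knockout 5, still differed by 20.1 times the sampling noise, so no library was counted as a duplicate. Alternatives covered the pseudocount, the filter on low values, 3 rescalings, robust and weighted fits, the range of mouse numbers as a covariate, voom on the recovered reads, and leaving out each library in turn. After the data were seen, 3 more were added: removing each library's trend with transcript length and GC, leaving out floxed control 4 and knockout 5 together, and the permutation test of list means. On the recovered reads, voom was the one test run; the planned quasi-likelihood and Wald tests were not. Python 3.11.15 with pandas 2.3.3 was used to read the table and matplotlib 3.10.9 to draw figures.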

Results

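Gene expression was measured by RNA-seq in fasted white quadriceps of 4 floxed control mice and 4 mice lacking Acot2 in muscle. Acot2 encodes a mitochondrial thioesterase that splits long-chain acyl-CoA into free fatty acid and coenzyme A. The title of the series places the enzyme in fatty acid oxidation of glycolytic muscle under different lipid supply, and the comparison asks how its loss alters the muscle transcriptome after a fast. Reads on genes numbered 32748272, 40977866, 32282222 and 40044496 in floxed controls 1 to 4 and 38612914, 32453532, 33658691 and 28659632 in knockouts 5 to 8. All values below are the authors' size-factor-normalized counts or their log2, and differences are knockout minus floxed control on the log2 scale, with the standard error (SE) of the limma fit and 4 mice per group.

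Acot2 transcript was lower in the muscle knockout, at 19.4% of the floxed control mean. Normalized counts of Acot2 (gene ID 171210) were 2406 ± 1099 (SD, n = 4) in floxed controls and 467 ± 130 (SD, n = 4) in knockouts. The gene lies on the plus strand of chromosome 12, from 83987861 to 83993873 in GRCm38, and its annotated transcript has 3 exons. Floxed controls 1 to 4 had 1675, 3927, 2492 and 1530 normalized counts of Acot2, and knockouts 5 to 8 had 413, 312, 600 and 543. The difference was -2.30 with an SE of 0.287 and a 95% interval from -2.94 to -1.67. All 4 knockouts lay below every floxed control, with an exact two-sided permutation p of 0.0286, the smallest this design allows. With the mouse number range as a covariate the permutation p was 0.05 for the same difference of -2.30, and without floxed control 4 and knockout 5 it was 0.1 (difference -2.44), so the call at 0.05 ended in both, where these are the smallest p the designs allow. Across the whole transcriptome the limma adjusted p of Acot2 was 0.087, the smallest of all genes and above the threshold of 0.05; it was 0.0042 without the filter on low values and ranged to 0.758 over the other settings. The sources used here do not say which exons are floxed, and counts per gene do not show where in the transcript the remaining reads fall. Acot1, a near-identical neighbour from 84009490 to 84018371, can share reads with Acot2, so both counts carry that uncertainty.

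**Figure D1:**
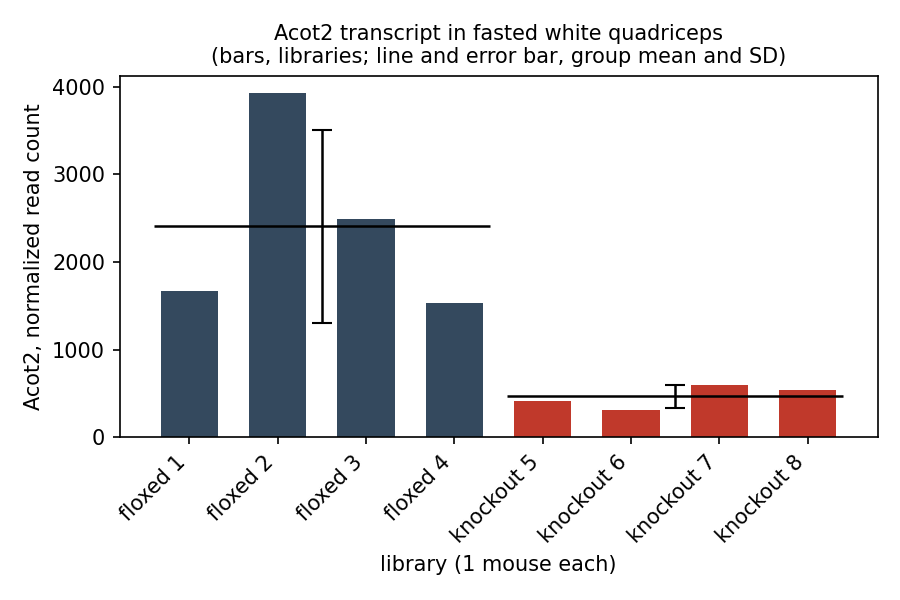
Normalized Acot2 read counts (y axis) in each of the 8 libraries (x axis), with group mean and SD drawn as a line and an error bar. The 4 knockout libraries lie between 312 and 600 counts and the 4 floxed controls between 1530 and 3927.

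Apart from Acot2, no single gene stood out from the spread between mice. With limma, 0 of 13141 tested genes passed an adjusted p of 0.05 and 1, Acot2, passed 0.1; the next smallest adjusted p was 0.746. At an unadjusted p under 0.05 there were 810 genes, 324 higher and 486 lower in the knockout, where chance alone gives 657. With voom on recovered reads the counts were 0 adjusted and 756 unadjusted. Scaling every library to the same total turned the unadjusted split from 40.0% to 66.7% higher. In 362 genes (2.75%) the 2 groups did not overlap, against 2.86% by chance. The unadjusted count depended on single libraries: it was 2200 without knockout 5 and 367 without floxed control 4, and 518, 422 and 456 without floxed control 1, knockout 6 and knockout 8. Without knockout 5, 143 genes passed an adjusted p of 0.1 and 0 passed 0.05.

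The 9 other genes with the smallest p all had an adjusted p of 0.746 (limma) and are given as values. Mat2a, which makes S-adenosylmethionine, differed by 0.54 (SE 0.116), with 250 ± 10.3 normalized counts (SD, n = 4) in floxed controls and 367 ± 45.05 (SD, n = 4) in knockouts. Nmrk2, a muscle nicotinamide riboside kinase that feeds NAD synthesis, differed by 1.41 (SE 0.354), and Fgfbp1, a carrier of fibroblast growth factors, by 1.01 (SE 0.257). Values were also higher for Atp2a3, a calcium pump of the endoplasmic reticulum (0.57, SE 0.138), and Mrpl16, a mitochondrial ribosomal protein (0.36, SE 0.0896). Lower values were found for the autophagy protein gene Atg16l2 (-0.67, SE 0.15), Zfp771 (-0.50, SE 0.115), Neurl4 (-0.38, SE 0.0916) and Pamr1 (-0.74, SE 0.184). In all of these but Nmrk2, the 4 knockouts lay beyond every floxed control, and for Nmrk2 this held for 3 of the 4. Genes picked for a small p tend to separate in this way, so the separation adds no support.

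As groups, nuclear genes of oxidative phosphorylation, the tricarboxylic acid cycle and mitochondrial beta-oxidation had higher values in 3 of the 4 knockouts than in every floxed control. For oxidative phosphorylation genes of the mitochondrial genome this held in 2 of the 4. Camera with its preset correlation called 15 of 37 lists, 14 higher and 1 lower, and no member of any list was called by itself. Adjusted over the list alone, 4 endothelial markers passed (Cldn5, Flt1, Vwf and Pecam1, each with an adjusted p of 0.0441 by limma) and 0 genes of every other list. None of the 15 calls held with an estimated correlation, where adjusted p ranged from 0.635 to 0.677 for these lists, nor with fry or with exact permutation of the list means. The smallest possible permutation p is 0.0286, so after adjustment over 37 lists a call would need many lists fully separated at once. For the 22 lists not called, adjusted p ranged from 0.635 to 0.936 with an estimated correlation, so where such a list is said below to pass in some setting, this is camera with the preset correlation. Floxed control 4 had the lowest mean of its group in 12 of the 15 lists and knockout 5 in 10 of them. Camera called 8 lists without floxed control 4 between 10 and 21 without any other single library, and 10 without both floxed control 4 and knockout 5.

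**Figure D2:**
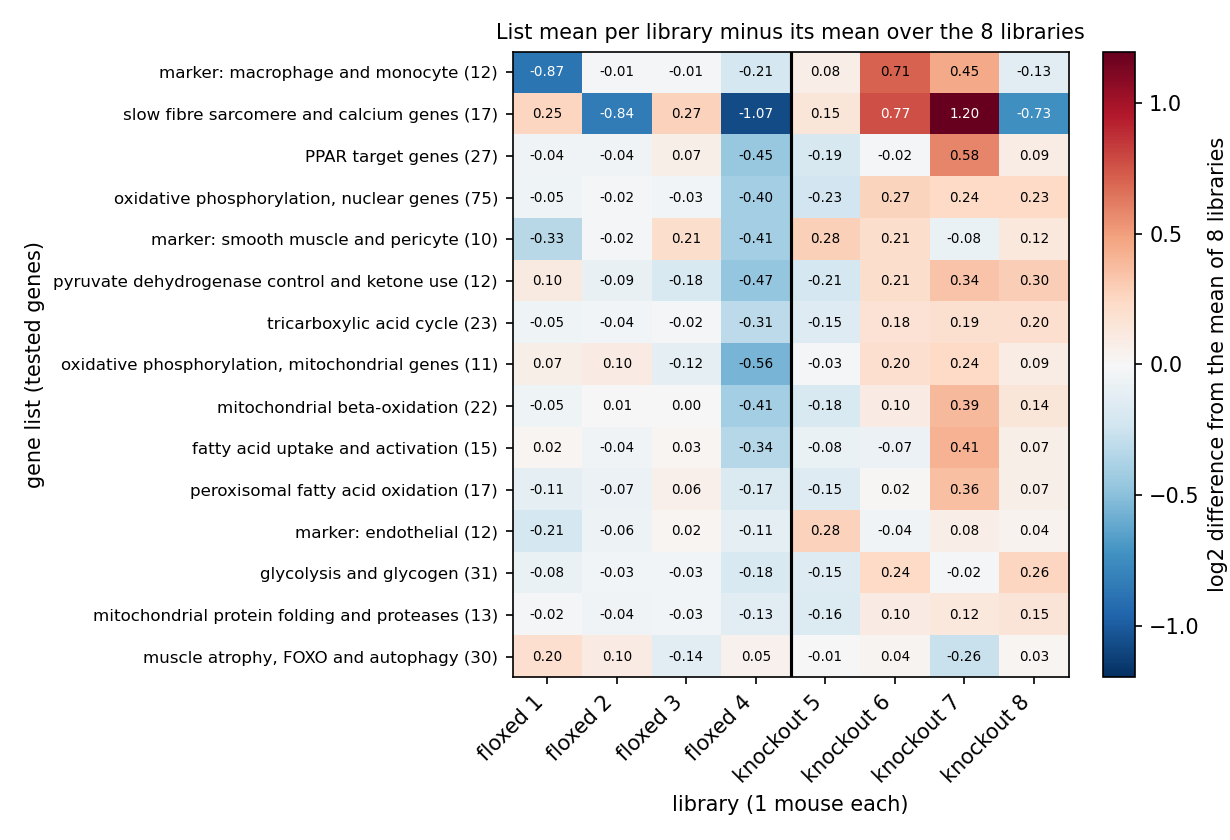
Mean log2 level of each of the 15 lists called by camera with the preset correlation (y axis, number of tested genes in brackets) in each library (x axis), minus the list's mean over the 8 libraries. Nuclear oxidative phosphorylation genes lay at 0.27, 0.24 and 0.23 in knockouts 6, 7 and 8, at -0.23 in knockout 5 and at -0.40 in floxed control 4.

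Genes of fatty acid oxidation had higher values in the knockout. Of 22 genes of mitochondrial beta-oxidation, 21 were higher and the median difference was 0.21; the list mean was 10.88 ± 0.199 (SD, n = 4) in floxed controls and 11.10 ± 0.233 (SD, n = 4) in knockouts. Its camera adjusted p was 1.62e-05 with the preset correlation and the adjusted p was 0.635 with an estimated correlation. The members with the smallest p were the short-chain acyl-CoA dehydrogenase gene Acads, at 0.46 (SE 0.149), and Acad9, at 0.24 (SE 0.0932). The 27 tested targets of PPAR receptors, which sense fatty acids, had a median of 0.28 with 25 higher (camera adjusted p = 0.000593), with Decr1 at 0.34 (SE 0.133) and the carnitine transporter gene Slc22a5 at 0.35 (SE 0.159). Peroxisomal oxidation genes had a median of 0.17 with 14 of 17 higher (camera adjusted p = 0.0104), with Crot at 0.29 (SE 0.104) and Pecr at 0.27 (SE 0.125). Fatty acid uptake and activation had a median of 0.20 with 13 of 15 higher (camera adjusted p = 0.0104), with Acsl4 at 0.29 (SE 0.0861) and the fatty acid transporter gene Cd36 at 0.34 (SE 0.169). For these 3 lists too, the adjusted p was 0.635 with an estimated correlation. In each of them, 2 of the 4 knockouts lay above every floxed control. The PPAR list shares genes with each of the other 3 lists, so the lists are not separate support. Beta-oxidation genes had their lowest means in floxed control 4 (10.58) and knockout 5 (10.81). Leaving out knockout 7 lowered the medians of PPAR targets, peroxisomal oxidation and uptake to 0.058, 0.040 and 0.049 and ended their calls (camera adjusted p of 0.218, 0.309 and 0.323). Knockout 7 also had the most Myh2, a myosin gene of fast oxidative fibres (59055 normalized counts), and a link with these lists was not tested. Leaving out floxed control 4 ended them too, with medians of 0.106, 0.130 and 0.141 (0.0547, 0.0547 and 0.117), and the uptake call also ended without both floxed control 4 and knockout 5 (0.076, median 0.166). The beta-oxidation median was 0.113 without floxed control 4 and 0.130 without knockout 7, with the call kept, and the peroxisomal median was 0.293 without knockout 5.

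Other lipid lists were not called. Triglyceride storage and lipolysis had 15 of 21 genes higher and a median of 0.14 (camera adjusted p = 0.117, adjusted p = 0.691 with an estimated correlation), with the lipid droplet genes Fitm1 at 0.20 (SE 0.11) and Fitm2 at 0.20 (SE 0.125); it passed without floxed control 3 (adjusted p = 0.0327), without knockout 6 (0.0133) and after removal of the length and GC trend (0.035, median 0.153), and its median was -0.0099 without knockout 7. Cholesterol synthesis had 13 of 22 higher and a median of 0.049 (camera adjusted p = 0.16, adjusted p = 0.691 with an estimated correlation), with Hsd17b7 at 0.47 (SE 0.143) and Insig1 at -0.32 (SE 0.109), and passed without floxed control 3 (0.0275, median 0.104), while the median was 0.0054 without floxed control 4 (0.749) and 0.120 without knockout 5 (0.237). Fatty acid synthesis had 10 of 17 higher; its median was 0.0011 while its mean was -0.044 and camera pointed downwards (adjusted p = 0.391). Fasn, the fatty acid synthase gene, was at -0.31 (SE 0.163) and Me1 at -0.20 (SE 0.111). Acyl-CoA thioesterases other than Acot2 had 6 of 8 tested genes higher and a median of 0.14 (camera adjusted p = 0.226), with Acot11 at 0.55 (SE 0.319) and Acot9 at 0.16 (SE 0.126); the median was 0.019 without knockout 7 (0.844) and 0.245 without knockout 5 (0.106).

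Respiratory chain and tricarboxylic acid cycle genes had higher values as groups. All 75 tested nuclear genes of oxidative phosphorylation were higher, with a median of 0.25; the list mean was 11.88 ± 0.185 (SD, n = 4) in floxed controls and 12.13 ± 0.237 (SD, n = 4) in knockouts, of which 3 lay above every floxed control. Camera gave an adjusted p of 1.16e-18 with the preset correlation, while the correlation estimated within the list was 0.927 and the adjusted p was 0.635 with an estimated correlation. Members with the smallest p were the complex I gene Ndufb5, at 0.42 (SE 0.163), and the complex III gene Uqcrfs1, at 0.37 (SE 0.146). The tricarboxylic acid cycle list had 21 of 23 genes higher and a median of 0.22 (camera adjusted p = 6.88e-07), with Dlat at 0.44 (SE 0.165) and Suclg1 at 0.29 (SE 0.109). This list also holds genes of pyruvate entry, among them the pyruvate dehydrogenase gene Dlat, and it shares Sdha, Sdhb, Sdhc and Sdhd with the nuclear list. All 11 tested genes of the mitochondrial genome were higher, with a median of 0.21 (camera adjusted p = 0.00487), with ND2 at 0.20 (SE 0.122) and ATP6 at 0.46 (SE 0.286). Both lists had an adjusted p of 0.635 with an estimated correlation, and the mitochondrial genome list lost its call without floxed control 4 (camera adjusted p = 0.159, median 0.084) and without both floxed control 4 and knockout 5 (0.159, median 0.155). The nuclear median was 0.163 without floxed control 4 and 0.381 without knockout 5, with the call kept. All 3 lists had their lowest means in floxed control 4 and, among knockouts, in knockout 5, the libraries with the largest shares of titin transcript in their groups (14.9% and 13.9% of normalized counts).

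Of 3 other lists of mitochondrial genes, 1 was called. Mitochondrial chaperones and proteases had 11 of 13 higher and a median of 0.087 (camera adjusted p = 0.0333, adjusted p = 0.677 with an estimated correlation), with Hspd1 at 0.28 (SE 0.131) and Htra2 at 0.26 (SE 0.149). That call ended without floxed control 2 (0.0559, median 0.111), floxed control 4 (0.137, median 0.078), knockout 7 (0.212, median 0.099) or knockout 8 (0.204, median 0.039), and, with the median as large, without the filter on low values (0.0681, median 0.087) and after removal of the length and GC trend (0.0646, median 0.090); without knockout 5 the median was 0.187 with the call kept. Mitochondrial biogenesis and dynamics had 16 of 24 higher and a median of 0.058 (camera adjusted p = 0.413), with the deacetylase genes Sirt3 at 0.46 (SE 0.176) and Sirt1 at -0.20 (SE 0.0941). Branched-chain amino acid breakdown had 13 of 19 higher and a median of 0.038 (camera adjusted p = 0.16, adjusted p = 0.75 with an estimated correlation), with Acad8 at 0.21 (SE 0.0931) and Hibch at 0.22 (SE 0.131); it passed without floxed control 1 (0.0125) and without knockout 6 (0.0207), while the median was -0.0039 without floxed control 4 (0.775) and 0.0043 without knockout 7 (0.965).

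Carbohydrate genes also had higher values. Glycolysis and glycogen genes were higher in 26 of 31, with a median of 0.13 (camera adjusted p = 0.00487, adjusted p = 0.666 with an estimated correlation). Pgam2, the muscle phosphoglycerate mutase gene, was at 0.49 (SE 0.15) and Pfkfb3, which controls phosphofructokinase, at -0.41 (SE 0.141). Genes of pyruvate dehydrogenase control and ketone use were higher in 11 of 12, with a median of 0.24 (camera adjusted p = 0.00638, adjusted p = 0.635 with an estimated correlation). Pdp2, a phosphatase that activates pyruvate dehydrogenase, was at 0.78 (SE 0.249) and Oxct1, which activates ketone bodies, at 0.29 (SE 0.121). The glycolysis call ended without knockout 6 (0.0515, median 0.059) or knockout 8 (0.144, median 0.064), and the pyruvate dehydrogenase call without floxed control 4 (0.0669, median 0.146) or knockout 7 (0.0518, median 0.161). Without knockout 5 the 2 medians were 0.215 and 0.362, with the calls kept.

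The list of muscle atrophy, FOXO and autophagy genes was the only one called lower. Of its 30 genes 27 were lower, with a median of -0.10 (camera adjusted p = 0.00727, adjusted p = 0.635 with an estimated correlation); 1 of 4 knockouts lay below every floxed control. Its 2 members with the smallest p were Igf1, a growth factor gene, at 0.41 (SE 0.131) and the ubiquitin ligase gene Fbxo31 at -0.23 (SE 0.105). The call ended without knockout 7 (0.3, median -0.071), floxed control 1 (0.136, median -0.109) or floxed control 2 (0.0559, median -0.074), and the median was -0.163 without floxed control 3 with the call kept.

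Stress and time-of-day lists were not called. The integrated stress response had 13 of 21 genes lower and a median of -0.098 (camera adjusted p = 0.117, 0.0385 with a stricter filter on low values, and 0.177 without knockout 6, where the median was -0.031; adjusted p = 0.635 with an estimated correlation), with the mitochondrial folate enzyme gene Aldh1l2 at -0.99 (SE 0.298) and Ppp1r15a at -0.22 (SE 0.0989). Antioxidant genes and NRF2 targets had 13 of 25 higher (camera adjusted p = 0.891, median 0.057), with Gpx3 at -0.40 (SE 0.133) and Gsr at -0.36 (SE 0.128). Glucocorticoid-responsive genes had 12 of 17 lower and a median of -0.058 (camera adjusted p = 0.153, adjusted p = 0.717 with an estimated correlation), with Zbtb16 at -0.23 (SE 0.108) and Angptl4 at 0.38 (SE 0.183); the list passed without floxed control 3 (0.0147), knockout 6 (0.0208) or knockout 8 (0.019), while the median was 0.030 without knockout 7 (0.869) and 0.0044 without floxed control 1 (0.622). Clock genes had 13 of 19 lower and a median of -0.12 (camera adjusted p = 0.251), with Cry2 at -0.30 (SE 0.124) and Bhlhe41 at 0.38 (SE 0.25); their median was -0.027 after removal of the length and GC trend (0.593), -0.028 without knockout 7 (0.727), -0.040 without floxed control 1 (0.318), -0.041 without floxed control 2 (0.574) and -0.067 without knockout 6 (0.411). Immediate early genes had 13 of 21 higher and a median of 0.076 (camera adjusted p = 0.895), with Jun at -0.21 (SE 0.0936) and Zfp36 at -0.47 (SE 0.226).

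Slow fibre genes had higher values in the knockout, with wide scatter between mice. Of 17 slow sarcomere and calcium genes 15 were higher, with a median of 0.51; the list mean was 6.68 ± 0.708 (SD, n = 4) in floxed controls and 7.37 ± 0.838 (SD, n = 4) in knockouts. The camera adjusted p was 0.00487, and the adjusted p was 0.635 with an estimated correlation. Myl3, a slow myosin light chain gene, was at 2.89 (SE 0.775) with 13.7 ± 14.7 normalized counts (SD, n = 4) in floxed controls and 69.6 ± 33.7 (SD, n = 4) in knockouts, and the calcium store gene Casq2 was at 0.60 (SE 0.24). Without knockout 7 the median fell to 0.071 and the call ended (0.218). It also ended without floxed control 2 (0.0591, median 0.198), without floxed control 4 (0.0669, median 0.230) and without both floxed control 4 and knockout 5 (0.159, median 0.374). Fast fibre genes, the bulk of this muscle, had 10 of 18 lower and a median of -0.0071 (camera adjusted p = 0.416, adjusted p = 0.795 with an estimated correlation); Ryr1, the calcium release channel gene, was at -0.52 (SE 0.208) and Mylk2 at -0.31 (SE 0.126), and the list passed without knockout 6 (0.0399), while its median was 0.093 without knockout 7 (0.572). Neuromuscular junction and denervation genes had 10 of 18 higher and a median of 0.052 (camera adjusted p = 0.895), with Runx1 at -0.66 (SE 0.26) and Dok7 at 0.56 (SE 0.245). Embryonic myosin and regeneration genes had 6 of 7 higher and a median of 0.43 (camera adjusted p = 0.12, adjusted p = 0.635 with an estimated correlation), with Myh3 at 1.92 (SE 0.924) and the myoblast fusion gene Tmem8c at 1.94 (SE 1.16), and passed without floxed control 2 (0.0379, median 0.708). Without knockout 6 the embryonic median fell to 0.140 (0.51), Myh3 to 0.73 and Tmem8c to 0.73; the list mean was 8.17 in knockout 6 and 6.01 to 6.19 in the other knockouts.

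Genes around the deleted locus showed no shared direction. Of 20 tested neighbours of Acot2 on chromosome 12, 11 were lower; the median was -0.021, the mean was 0.042 and the camera adjusted p was 0.895. Ptgr2 was at 0.45 (SE 0.183) and Coq6, an enzyme gene of coenzyme Q synthesis, at 0.25 (SE 0.127).

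Markers of macrophages, endothelium and smooth muscle had higher values in the knockout, while all 8 tendon markers had lower ones. All 12 tested macrophage and monocyte markers were higher, with a median of 0.53; the list mean was 6.99 ± 0.408 (SD, n = 4) in floxed controls and 7.55 ± 0.375 (SD, n = 4) in knockouts (camera adjusted p = 5.69e-06). Adgre1, which encodes F4/80, was at 1.02 (SE 0.328) and the complement gene C1qa at 0.73 (SE 0.237). Endothelial markers were higher in 10 of 12, with a median of 0.16 (camera adjusted p = 0.00273), Cldn5 at 0.73 (SE 0.213) and Flt1 at 0.28 (SE 0.0875). Smooth muscle and pericyte markers were higher in 7 of 10, with a median of 0.24 (camera adjusted p = 0.0304), Myh11 at 0.44 (SE 0.171) and Kcnj8 at 0.30 (SE 0.137). For all 3 lists the adjusted p was 0.635 with an estimated correlation. The endothelial call ended without knockout 5 (0.161, median 0.114) and without both floxed control 4 and knockout 5 (0.165, median 0.117). The smooth muscle call ended while its median stayed between 0.193 and 0.297: without floxed control 1 (0.119, median 0.234), floxed control 4 (0.083, median 0.196), knockout 5 (0.253, median 0.297) or both of the latter (0.417, median 0.193), and with library weights (0.115, median 0.268). The macrophage median was 0.334 without knockout 6, with the call kept.

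The tendon list had a median of -0.49 (camera adjusted p = 0.0585, adjusted p = 0.635 with an estimated correlation), with Mkx at -1.01 (SE 0.537) and Kera at -0.70 (SE 0.439). It passed without floxed control 3 (0.00667), knockout 6 (0.0401) or knockout 7 (0.0121), on rescaling to the same total (0.0237), with the mouse number covariate (0.013) and after removal of the length and GC trend (0.0473). Its median was -0.225 without knockout 8 (0.305) and -0.731 without knockout 7. Fibroblast and matrix markers were higher in 13 of 16, with a median of 0.15 (camera adjusted p = 0.0585, adjusted p = 0.691 with an estimated correlation), Postn at 0.98 (SE 0.556) and Fn1 at 0.28 (SE 0.176). They passed without floxed control 3 (0.0283), floxed control 4 (0.0228), knockout 7 (0.0386) or knockout 8 (0.000999), with a stricter filter on low values (0.0458) and after removal of the length and GC trend (0.0336, median 0.186). Their median fell to 0.049 without knockout 6 (0.894) and to 0.061 without floxed control 1 (0.488); knockout 6 had the highest list mean, 11.17. Schwann cell markers were higher in 7 of 8, with a median of 0.09 (camera adjusted p = 0.0737, adjusted p = 0.635 with an estimated correlation), with Sox10 at 0.65 (SE 0.429), and passed without floxed control 1 (0.00519, median 0.166) or knockout 8 (0.0095, median 0.193), while the median was 0.0073 without knockout 7 (0.271), 0.044 without floxed control 4 (0.305) and 0.059 without knockout 6 (0.0786). Red blood cell genes had a median of 0.27 (camera adjusted p = 0.25, adjusted p = 0.75 with an estimated correlation), with the globin gene Hbb-bs at 0.29 (SE 0.369), and passed without floxed control 3 (0.000239, median 0.688), while the median was -0.063 without floxed control 4 (0.844). Satellite cell markers had 5 of 8 lower and a median of -0.11 (camera adjusted p = 0.483), with Vcam1 at -0.50 (SE 0.255) and Chodl at -0.22 (SE 0.184). Adipocyte markers (5 of 9 higher, median 0.14, Fabp4 at 0.14 with SE 0.139, Pparg at -0.23 with SE 0.237) and myofibre markers (5 of 10 higher, median 0.044, Ckmt2 at 0.65 with SE 0.264, Eno3 at 0.34 with SE 0.206) had a camera adjusted p of 0.895. Lymphocyte markers were not tested as a list, since Ighm alone passed the filter, at 0.72 (SE 0.338), and 0 neutrophil markers did.

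The libraries also differed in the level of long transcripts, and this difference went along with the mitochondrial genes. The titin gene Ttn, whose transcript is very long, took 12.8%, 11.8%, 12.2% and 14.9% of normalized counts in floxed controls 1 to 4, 13.9% in knockout 5 and 8.67%, 8.34% and 9.22% in knockouts 6 to 8. Across 12722 genes, which are not independent replicates, the difference between knockout and floxed control had a Spearman correlation of -0.205 with transcript length. The median difference was 0.076 in the quintile of genes with the shortest transcripts and -0.063 in that with the longest. Over the 8 libraries, each library's slope of expression on length and its mean over nuclear oxidative phosphorylation genes had a Pearson r of -0.888 (permutation p = 0.00238, adjusted p = 0.00476) and a Spearman rho of -0.905 (permutation p = 0.00456, adjusted p = 0.00913), 1 of 2 such relations computed. Without floxed control 4 and knockout 5, the libraries farthest from the median slope, r was -0.772. With each genotype's mean removed, r was -0.851 (permutation p within genotypes = 0.0191, adjusted p = 0.0382). The labels give no batch within which to repeat this. Nuclear oxidative phosphorylation genes have short transcripts (median 1141 bases, against 3395 over tested genes) and were among the genes that set the slope. A negative relation is therefore partly built in, and its p-values do not show a link between 2 separate measures.

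**Figure D3:**
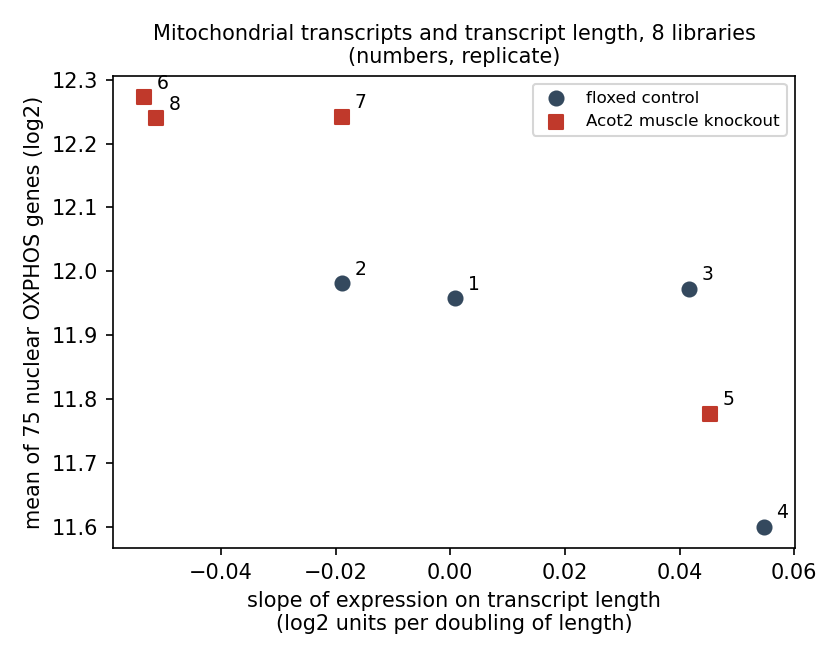
Mean log2 level of the 75 nuclear oxidative phosphorylation genes (y axis) against the slope of expression on transcript length (x axis, log2 units per doubling of length) in each of the 8 libraries, numbered by replicate. Knockouts 6, 7 and 8 have the highest gene means, while knockout 5 lies with floxed control 4 at the lowest.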

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

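Removal of the length and GC trend, with its matched lists, and the rescaling without the 10 most abundant genes were chosen after the data were seen. Tests chosen only after the results were seen were the permutation tests of list means against genotype, the comparison of macrophage with tendon markers, the relation of slow genes with Myh2, the relations within genotypes and the count of splits for genes past the adjusted threshold.

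Of 250 sets of 4 replicates, 24 had 1 mouse far from its 3 group mates relative to the group's range, where chance gives about 5% (1 in 20) for independent sets. The sets overlap, since list means stand beside genes of the same lists, so the 24 do not count as separate evidence. Most of the 24 were floxed control 4 or knockout 5, and both were low in mitochondrial genes. Mean log2 levels of nuclear oxidative phosphorylation genes were 11.60 in floxed control 4 (others 11.96 to 11.98) and 11.78 in knockout 5 (others 12.24 to 12.27). Tricarboxylic acid cycle genes were at 12.50 in floxed control 4 (others 12.77 to 12.79) and 12.66 in knockout 5 (others 12.99 to 13.01). Beta-oxidation genes were at 10.58 in floxed control 4, and mitochondrial chaperones and proteases at 10.82 in knockout 5. Among single genes, some of them members of these lists, Uqcrfs1 was at 12.55 in floxed control 4 and 12.87 in knockout 5, and Hibch at 9.69 in both. Suclg1 was at 12.11 and Cd36 at 13.08 in floxed control 4, and Ndufb5 at 11.93 in knockout 5. Long transcripts stood out the other way in knockout 5, with Ttn at 13.85% of normalized counts (other knockouts 8.34% to 9.22%) and Ryr1 at 17.94 (others 17.04 to 17.16).

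Knockout 6 stood apart in genes of muscle regeneration. Its mean over the embryonic myosin list was 8.17, against 6.01 to 6.19 in the other knockouts, and its log2 level of Tmem8c was 6.25, against 0.95 to 1.77. It held 2526 normalized counts of Myh3, the embryonic myosin gene, where the other 7 libraries held between 39.1 and 124.8. Knockout 7 had the lowest mean of atrophy genes, 12.17 against 12.43 to 12.47 in the other knockouts, and the highest Kcnj8, 8.90. Knockout 5 was also low in the red blood cell list at 7.25, in Hbb-bs at 10.28 and in Atp2a3 at 7.79. Among floxed controls, Cldn5 was at 8.69 in floxed control 2 and Adgre1 at 4.80 in floxed control 1.

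Nuclear oxidative phosphorylation genes had higher values in the knockout, with a median difference of 0.25 over 75 genes. After each library's trend with transcript length and GC was removed the median was 0.194, which argues against the length trend as the whole cause. Before removal, the median of 0.25 lay above 100% of 10000 random lists matched on length, GC and expression (median 0.074). Each random list drew its genes singly, while genes of this list move together (estimated correlation 0.927). The percentile therefore cannot tell a list effect from shared scatter between mice, and the uncalled fibroblast list also reached 100%. Over 4 rescalings, 1 of them without the 10 most abundant genes, the lowest median was 0.247, which argues against a few abundant transcripts setting the scale. The deposited size factors made this outcome likely, since rescaling by median ratio hardly moved the median (0.252). Scaling to the same total, where abundant transcripts weigh most, gave 0.293. The list mean did not separate the genotypes (exact permutation p = 0.114), since knockout 5 lay below 3 of the floxed controls, so an effect of genotype stays open. A candidate explanation that stays open as well is a difference in tissue or RNA between mice that acts on mitochondrial genes beyond transcript length.

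Macrophage and monocyte markers had higher values in the knockout, with a median difference of 0.53 over 12 genes, 0 of them in another list, led in level by Lyz2 (9.44 in floxed controls and 9.99 in knockouts, mean log2). Leaving out any 1 library gave medians no lower than 0.334, which argues against a single mouse as the whole source. The list mean was lowest in floxed control 1 (6.40, other floxed controls 7.07 to 7.26) and highest in knockout 6 (7.98), while knockout 8 (7.14) lay within the range of the floxed controls. A fit without both floxed control 1 and knockout 6 was not run, so a source in these 2 mice together stays open. If a lower share of myofibre RNA raised markers of all other cells alike, the macrophage mean minus the tendon mean would be the same in both groups. That difference per library had an exact permutation p of 0.0857 between the groups. The tendon list was picked after all 8 of its markers were seen to be lower, so this test cannot decide and leaves a lower myofibre share open. Genotype stays open too (exact permutation p = 0.114), with 3 of 4 knockouts above every floxed control.

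Slow fibre genes had a median difference of 0.51 over 17 genes, with Myl3 at 2.89. The list median was 0.071 without knockout 7, 0.198 without floxed control 2 and 0.230 without floxed control 4, so its size depends on single mice. If the dissected pieces varied in their share of oxidative fibres, Myh2, a myosin of fast oxidative fibres, should follow the slow list; the Spearman rho over 8 libraries was 0.381 (permutation p = 0.36, adjusted p = 0.36 over 2 relations) and Pearson's r was 0.687 (permutation p = 0.0575, adjusted p = 0.0575), or 0.605 without floxed controls 2 and 4. Pearson's r was 0.987 in the 4 floxed controls, 0.671 in the 4 knockouts and 0.774 with each genotype's mean removed (permutation p within genotypes = 0.0694, adjusted p = 0.0694), while Myh2 itself differed between the groups by -0.009 (SE 0.809). This does not decide between a mixed dissection and a change within fibres, and genotype stays open (exact permutation p = 0.257), with 2 of the 4 knockouts above every floxed control.

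Other splits of the 8 libraries into 4 and 4 gave counts as large for genes at an unadjusted p and for lists. For genes past an adjusted p of 0.05 the real split gave 0, which every split reaches, so this count says nothing about chance; the highest of the others gave 62. For genes at an unadjusted p under 0.05, 8 of the 35 splits reached the real count of 810, and the highest of the others gave 2763. For lists called by camera with the preset correlation, 8 of the 35 splits reached the real count of 15, and the highest of the others gave 20. Chance is therefore not excluded for the unadjusted genes or the lists. The split with 2763 genes put floxed controls 1, 3 and 4 with knockout 5 against the rest. It was picked as the largest of the others and keeps most libraries with their own genotype, and its cause was not tested.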

How the results depend on the processing

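The permutation of list means, removal of the length and GC trend and the fit without floxed control 4 and knockout 5 were chosen after seeing the data; the rest were set beforehand. Acot2 stayed lower in every setting, from -2.49 to -2.03 over the leave-one-out fits. Its permutation p was 0.05 with the mouse number range as a covariate (difference -2.30) and 0.1 without floxed control 4 and knockout 5 (-2.44), each the smallest p those designs allow. Its limma adjusted p ranged from 0.0042 to 0.758. The count of genes past the adjusted threshold was 1, Acot2, without the filter on low values, where more genes inform the fit, and 1 at an adjusted p of 0.1; it was 0 in each leave-one-out fit. The count at an unadjusted p under 0.05 was 1362 without the filter (more genes tested), 1467 with library weights and 1509 without floxed control 4 and knockout 5, and ranged from 367 (without floxed control 4) to 2200 (without knockout 5) over the leave-one-out fits; the cause was not tested. Called lists numbered 0 with an estimated correlation, where camera enlarges a list's variance by its own correlation. They numbered 0 by fry and 0 by permutation of list means, whose smallest p of 0.0286 leaves little room for a call after adjustment. Over the leave-one-out fits they ranged from 8 (without floxed control 4) to 21 (without floxed control 3). The share of higher genes among those at an unadjusted p under 0.05 was 40.0%, and 66.7% on rescaling to the same total, 53.4% after trend removal. Robust eBayes gives no camera or permutation value, and voom was run for gene counts only. A quasi-likelihood test (edgeR) and a Wald test (DESeq2) on the recovered reads were planned and were not run, so voom alone stands for tests on reads.

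Directions turned for some lists that were not called; the cause was not tested. On rescaling to the same total, the medians were 0.034 for fast fibre genes and 0.021 for neighbours of Acot2. With library weights they were -0.0135 for fatty acid synthesis and -0.0133 for adipocyte markers. After trend removal the antioxidant median was -0.0076, and medians that kept their direction moved by over 1.5 times to -0.027 for clock genes, -0.047 for satellite cell markers, 0.0074 for branched-chain amino acid breakdown, 0.022 for cholesterol synthesis, 0.084 for acyl-CoA thioesterases, 0.058 for fatty acid synthesis, -0.035 for fast fibre genes, 0.034 for neuromuscular genes, 0.010 for myofibre markers and -0.0064 for neighbours of Acot2. Without floxed control 4 and knockout 5 the medians were -0.00020 for antioxidant genes, 0.0052 for fast fibre genes, -0.0203 for neuromuscular genes and -0.0132 for adipocyte markers. Over the leave-one-out fits, medians ranged from -0.0099 to 0.213 for triglyceride storage, -0.0886 to 0.0471 for fatty acid synthesis, -0.0039 to 0.090 for branched-chain amino acid breakdown, -0.0076 to 0.10 for mitochondrial biogenesis, -0.0138 to 0.127 for antioxidant genes, -0.173 to 0.0304 for glucocorticoid-responsive genes, -0.145 to 0.17 for immediate early genes, -0.0761 to 0.0934 for fast fibre genes, -0.0381 to 0.119 for neuromuscular genes, -0.0837 to 0.0284 for neighbours of Acot2, -0.051 to 0.125 for myofibre markers, -0.387 to 0.305 for adipocyte markers and -0.0628 to 0.688 for red blood cell genes; Hbb-bs ranged from -0.038 to 0.673. Uncalled lists that kept their direction also moved over the leave-one-out fits: medians ranged from 0.019 to 0.245 for acyl-CoA thioesterases, 0.0054 to 0.120 for cholesterol synthesis, -0.121 to -0.031 for the integrated stress response, -0.148 to -0.028 for clock genes, 0.140 to 0.834 for embryonic myosin and regeneration, 0.049 to 0.212 for fibroblast markers, -0.731 to -0.225 for tendon markers, 0.0073 to 0.193 for Schwann cell markers and -0.278 to -0.025 for satellite cell markers. The 15 called lists kept their direction in each setting that gave them a value; the mitochondrial genome list has no value after trend removal, since none of its genes had a matched length. Of these lists, 4 kept their call in each leave-one-out fit: beta-oxidation, the tricarboxylic acid cycle, nuclear oxidative phosphorylation and macrophage markers. Some named genes of uncalled lists moved as well over the leave-one-out fits. Postn ranged from 0.372 to 1.37, Fn1 from 0.091 to 0.399, Mkx from -1.28 to -0.514 and Kera from -1.01 to -0.438. Acot11 ranged from 0.255 to 0.727 and Acot9 from 0.080 to 0.274. In the called macrophage list, Adgre1 ranged from 0.630 to 1.17. Genes with few counts, such as Tmem8c at a mean of 0.80 in floxed controls, have fold changes that depend on the pseudocount.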

Other observations

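The genes in this part were chosen after their values were seen. Pdk4 and Ucp3, 2 genes induced by fasting, differed by less than the spread between mice. Pdk4, which blocks pyruvate dehydrogenase during fasting, had 214827 ± 13674 normalized counts (SD, n = 4) in floxed controls and 218045 ± 19515 (SD, n = 4) in knockouts, a difference of 0.019 (SE 0.138). Ucp3, a mitochondrial uncoupling protein gene, was at 10153 ± 1507 (SD, n = 4) and 11086 ± 1702 (SD, n = 4). Angptl4, also induced by fasting, which encodes an inhibitor of lipoprotein lipase, was at 589 ± 49.2 (SD, n = 4) and 791 ± 211 (SD, n = 4), a difference of 0.38 (SE 0.183, limma adjusted p = 0.746), with 3 of 4 knockouts above every floxed control. All 3 genes are in the list of PPAR targets above. Fgf21, a secreted marker of mitochondrial stress, had 0 reads in every library, and Gdf15 had between 0 and 2 reads per library. The other thioesterases of the cluster were scarce: Acot1 had 123 ± 60.5 (SD, n = 4) and 213 ± 207 (SD, n = 4) normalized counts, with 519 in knockout 7, Acot6 had 43.8 ± 6.41 (SD, n = 4) and 39.4 ± 29.2 (SD, n = 4), and Acot5 had 0 reads in every library.

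Myosin heavy chain genes differed between the pieces of muscle, with no group apart from the other. Myh4, the myosin of fast glycolytic fibres, led in every library, with 2357010 ± 377871 (SD, n = 4) normalized counts in floxed controls and 2159000 ± 561534 (SD, n = 4) in knockouts. Myh2 ranged from 4421 to 18567 counts in floxed controls, while knockout 7 had 59055 and the other knockouts between 4005 and 7087. Slow Myh7 was scarce, with 302.9 counts in knockout 5, 135.9 in knockout 7 and 83.6 in floxed control 1.

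The nuclear RNAs Malat1 and Neat1 set the same 2 libraries apart that were low in mitochondrial genes. Malat1 had 92399 normalized counts in floxed control 4 and 97194 in knockout 5, against 43880 to 59863 in the other 6 libraries. Neat1 had 31330 in floxed control 4 and 33951 in knockout 5, against 10388 to 15454 elsewhere. No explanation of this was tested.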
